A study of Rattus norvegicus with 39 samples.

How the data were processed

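Gene expression was measured on Affymetrix rat arrays hybridised with RNA from laser-captured liver tissue. Rats aged 8 weeks received 1 oral dose of alpha-naphthyl isothiocyanate (ANIT), a compound used to injure bile ducts in rodents, at 50 mg per kg in corn oil, or corn oil alone at 10 ml per kg. Tissue was taken 2 or 6 h later, and either bile duct or hepatocytes were captured from sections. This made 8 groups with 39 arrays. Each group held 5 arrays, except vehicle bile duct at 6 h with 4. The labels state separate rats within a group. They number bile duct and hepatocyte arrays in parallel but do not say whether a bile duct array and a hepatocyte array came from 1 animal, so no pairing was used.

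The values used here are log2 probe set intensities from the deposited series matrix, made by the authors with RMA (background correction, quantile normalization and median polish) per the labels. Neither the version nor whether 1 run held every array is stated. The authors' deposited comparison tables, 1 per time and captured region, give log10 ratios of ANIT over vehicle. The authors' deposited tables also give a p-value per probe set from Rosetta Resolver, with no statement of adjustment. Changes from the matrix and from the authors' deposited tables, both as log2, correlated across probe sets at 0.76 and 0.66 (2 h bile duct and hepatocytes) and 0.79 and 0.64 (6 h), so they were not the same measure of change. Values ran from 0.9 to 14.21, and array means from 4.42 to 4.54. Array data carry no counts, so the number of arrays limits the precision.

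Of 15923 probe sets, 57 array controls were left out and 15866 were tested. A supplied table gave 1 gene symbol for 12783 of these probe sets and several for 312, and 2771 were not listed and are not named. Of the probe sets with an identifier, 12748 had one that the supplied RefSeq table also holds. No coordinates were used.

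Each comparison of ANIT with vehicle was fitted on its own arrays in R 4.3.3 with limma 3.58.1 (group means, moderated t-statistics by eBayes, no covariates, two-sided). Differences of the ANIT effect between captured regions or between times were interaction contrasts over the 4 groups concerned. Adjusted p denotes Benjamini-Hochberg adjustment over the 15866 probe sets, with a threshold of 0.05. Gene lists, 36 in all, were written and fixed before the data were examined, as were the comparisons, tests, thresholds, the rule for naming genes and the first set of alternatives. Each gene of a list was represented by its probe set with the highest mean over the 39 arrays. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Camera compares a list with the other genes, whereas fry asks whether the list's own genes move. List p-values were adjusted over the 36 lists, and counts of members are given adjusted over all probe sets and adjusted over the list alone.

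Genes were named by rule. For each ANIT comparison these were the 10 largest rises and 10 largest falls among probe sets past the threshold with every ANIT array on 1 side of the vehicle mean. Where none passed, they were the 5 rises and 5 falls with the smallest unadjusted p. Up to 4 members with the smallest p were named for each list described, and for each interaction the 5 probe sets per direction with the smallest adjusted p. Errors given with log2 changes are standard errors from limma, and those given with group means or array measures are standard deviations.

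Measures of each array (mean, spread, mean correlation with its group, 3' and 5' control probe sets, repeat and ribosomal RNA probe sets, and mean levels of cell type markers) were compared between ANIT and vehicle arrays with exact two-sided permutation tests, with Benjamini-Hochberg adjustment over the measures of each comparison. The fits were tested on simulated data with known 2-fold and 4-fold changes added to arrays of 1 group.

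Alternatives changed 1 choice at a time. They were quantile normalization again over the arrays of each comparison, subtraction of array medians, removal of dim probe sets, and eBayes with trend and robust. Further ones were array weights, 1 fit over all 39 arrays, 1 probe set per gene and a replicate block (statmod 1.5.0 for its random form). The last were the authors' p-values after adjustment, an added 1.5-fold threshold, an adjusted p under 0.01, and each array left out in turn. Added after the data had been seen were a fit of all 4 bile duct groups, the same fit with each array's spread or hepatocyte marker level as a covariate, spread as a covariate within each region in a fit of all 39 arrays for the region tests, removal of the 2 bile duct arrays of low spread after ANIT at 2 h, the 2 h vehicle bile duct arrays as controls at 6 h, and the 3' minus 5' GAPDH difference as a covariate. The arrays of each comparison were also divided in 100 drawn ways to count how often another division gave as large a result.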

Results

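RNA from laser-captured bile duct or hepatocytes of rat liver was measured on 39 arrays, 2 or 6 h after a single oral dose of ANIT (50 mg per kg) or of its corn oil vehicle. There were 5 arrays in each of 7 groups and 4 in the vehicle bile duct group at 6 h. Within groups, hepatocyte arrays were closely alike, with pairwise correlations across probe sets from 0.979 to 0.993. Bile duct arrays varied more, from 0.834 to 0.893 in the 6 h vehicle group, 0.918 to 0.947 with ANIT at 6 h, 0.866 to 0.959 with ANIT at 2 h and 0.939 to 0.973 in the 2 h vehicle group. At 2 h the mean correlation with arrays of the same group was 0.918 with ANIT and 0.956 with vehicle. Values within a group share pairs of arrays, so the exact permutation test (p = 0.00794, BH 0.143) cannot measure this difference. The 3' actin signal of ANIT replicates 2 and 4 was 7.07 and 7.66, against 9.15 to 10.24 on the other 3.

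What each captured region held was examined in vehicle rats. At 2 h all 18 markers of cholangiocytes, the epithelial cells of bile ducts, were higher in bile duct than in hepatocyte captures, with a median log2 difference of 4.57 (camera adjusted p = 1.24e-13, and adjusted p = 0.0229 with an estimated correlation). The keratin gene Krt19 stood at 11.50 ± 0.07 (SD, n = 5) in bile duct and 3.65 ± 0.15 (n = 5) in hepatocytes, 231-fold higher. At 6 h 17 of the 18 were higher, with a median of 3.55 (adjusted p = 2.67e-11, and adjusted p = 0.143 with an estimated correlation). All 18 hepatocyte markers were lower in bile duct at both times, with medians of -6.34 at 2 h and -4.09 at 6 h (camera adjusted p = 1.33e-10 and 2.65e-05, and adjusted p = 0.213 and 0.372 with an estimated correlation). The bile acid uptake transporter gene Slc10a1 was 99.6-fold lower in bile duct at 2 h and 38.8-fold lower at 6 h. Hepatocyte marker RNA was still measured in bile duct captures, at a mean level of 5.66 at 2 h and 7.29 at 6 h, against 11.26 and 11.14 in hepatocyte captures.

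Connective tissue markers also differed between the regions. Of 20 fibroblast, stellate and smooth muscle markers, 12 were higher and 2 lower in bile duct at 2 h (camera adjusted p = 0.0159, and adjusted p = 0.544 with an estimated correlation), and 11 were higher and 2 lower at 6 h (adjusted p = 0.00423, and adjusted p = 0.166 with an estimated correlation). The collagen gene Col1a1 was 30.9-fold higher at 2 h and 15.4-fold higher at 6 h, while the stellate cell genes Reln and Lrat were lower in bile duct at 2 h. Macrophage markers were mixed, since the Kupffer cell receptor gene Clec4f was 99.2-fold lower in bile duct at 2 h whereas Cd74, of antigen presentation, was 8.00-fold higher. In all, 8286 of 15866 probe sets differed between regions at 2 h (4553 higher in bile duct) and 8515 at 6 h (4643 higher). Quantile normalization lowered the 6 h count to 5428, and without dim probe sets 42.1% of 5412 were higher at 2 h and 24.7% of 4773 at 6 h.

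The first ANIT comparison asked what had changed in bile duct 2 h after the dose. Hmox1, encoding the heme-degrading enzyme heme oxygenase, rose by 4.13 ± 0.73 on the log2 scale, 17.5-fold (n = 5 and 5, adjusted p = 0.0172). The ANIT arrays ran from 5.53 to 10.45 and the vehicle arrays from 4.24 to 4.68, without overlap. Srxn1, encoding the peroxiredoxin-repairing enzyme sulfiredoxin, rose 10.1-fold (3.34 ± 0.61, adjusted p = 0.0197). Irgm2, an interferon-inducible GTPase gene, fell 7.87-fold with the smallest p of the comparison (-2.98 ± 0.27, adjusted p = 0.000156). Hbegf, a growth factor that activates the EGF receptor, rose 8.59-fold (3.10 ± 0.65, adjusted p = 0.0353), but did not pass with quantile normalization (adjusted p = 0.0584). Cyp1a1, a xenobiotic cytochrome induced through the aryl hydrocarbon receptor, fell from 8.43 ± 0.39 to 5.24 ± 1.84 (SD), 9.11-fold (log2 change -3.19 ± 0.64, adjusted p = 0.0264). This call was lost with quantile normalization (adjusted p = 0.0662). In a fit of the 4 bile duct groups it was kept (adjusted p = 0.041), and lost with array spread (adjusted p = 0.0743) or hepatocyte markers (adjusted p = 0.0563) as a covariate there. The authors' deposited table gave a 2.5-fold lower value for Cyp1a1 (p = 0.0569).

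Other large rises were in the aldo-keto reductase gene Akr1b8 (11.6-fold), the thioredoxin reductase gene Txnrd1 (6.47-fold), the ERK phosphatase gene Dusp5 (6.00-fold), the receptor kinase gene Epha2 (5.48-fold) and the chaperone gene Hsph1 (4.82-fold). The lipoprotein receptor gene Lrp8 (4.53-fold) and Nab2 (4.23-fold), a corepressor of EGR factors, rose as well. Their adjusted p ran from 0.0168 to 0.0471. Vehicle means of Txnrd1 (3.00), Dusp5 (2.76) and Lrp8 (2.29), like that of Hbegf (3.11), were low, so the sizes of these rises are not well measured. Other large falls were in Rprm (5.45-fold), a regulator of the cell cycle, the glutamate transporter gene Slc1a3 (5.33-fold), the retinal reductase gene Dhrs3 (5.18-fold) and the calcium sensor gene Ncald (4.97-fold). The next were Rasl11b (4.76-fold), the sestrin gene Sesn1 (4.61-fold), the MYC antagonist gene Mxi1 (4.60-fold) and the phosphate transporter gene Slc34a2 (4.57-fold), with adjusted p from 0.00708 to 0.0353. Other probe sets of Slc1a3 changed by -0.35 and, in the opposite direction, 0.49, neither passing, another of Txnrd1 changed by 1.56 (adjusted p = 0.0665), and another of Mxi1 changed by -0.13 (adjusted p = 0.832).

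Among the fixed lists, 4 of 23 NRF2 targets and glutathione synthesis genes rose, none fell and 19 did not pass. When adjusted over the list alone 11 rose (median 0.90, camera adjusted p = 8.1e-08, and adjusted p = 0.551 with an estimated correlation). Its members with the smallest p were Hmox1, Srxn1, the growth inhibitor gene Osgin1 (3.66-fold higher) and the UDP-glucose dehydrogenase gene Ugdh (2.25-fold higher). Of 16 MAPK feedback and EGFR ligand genes, 3 rose and 13 did not pass, with 8 rising when adjusted over the list alone (median 1.02, adjusted p = 3.13e-07, and adjusted p = 0.149 with an estimated correlation). These were Hbegf, Dusp5 and Dusp6, also an ERK phosphatase gene (2.35-fold), and Phlda1 was 3.07-fold higher without passing (adjusted p = 0.0633). Of 24 immediate early genes, 3 rose, the transcription factor genes Egr1 (2.77-fold) and Csrnp1 (2.79-fold) and Ier2 (2.61-fold), and 21 did not pass. With adjustment over the list alone 6 rose (median 0.50, adjusted p = 9.65e-05, and adjusted p = 0.48 with an estimated correlation), and Atf3, a stress-induced transcription factor gene, was 9.27-fold higher without passing (adjusted p = 0.0633).

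Of 17 heat shock genes, 1 rose (Hsph1) and 16 did not pass, with 4 rising when adjusted over the list alone (median 0.88, camera adjusted p = 9.37e-06, and adjusted p = 0.638 with an estimated correlation). The inducible chaperone gene Hspa1a was 9.93-fold higher without passing (adjusted p = 0.0507). Of 19 ribosome biogenesis genes, 2 rose, Rrp9 (2.57-fold) and Tsr1 (2.92-fold), which act in the making of ribosomal subunits, and 17 did not pass. Adjusted over the list alone 6 rose (median 0.61, adjusted p = 4.97e-06, and adjusted p = 0.551 with an estimated correlation). Interferon targets were lower as a list, with 1 of 18 falling, the antiviral gene Rsad2 (-1.09 ± 0.25), and 17 not passing. Of these 18, 5 fell when adjusted over the list alone (median -0.39, adjusted p = 0.00287, and adjusted p = 0.149 with an estimated correlation). In the list of NF-kB targets and chemokines 2 of 29 fell, the interferon regulatory factor gene Irf1 (-1.63 ± 0.29) and the apoptosis inhibitor gene Birc3 (-2.04 ± 0.46). The list did not pass (adjusted p = 0.294). In the list of p53 targets 1 of 10 fell (Sesn1), the cell cycle inhibitor gene Cdkn1a was 2.99-fold higher without passing (adjusted p = 0.196), and the list did not pass (adjusted p = 0.544). Of the 19 list members named as passing at 2 h, 16 passed with quantile normalization and 13 in the fit of the 4 bile duct groups without a covariate, which did not keep Egr1, Ier2, Csrnp1, Birc3, Rrp9 and Rsad2. In that fit 11 passed with the spread covariate and 11 with the hepatocyte marker covariate. With fry the MAPK feedback list (adjusted p = 0.0261) and the interferon targets (adjusted p = 0.00725) passed. The other 9 lists past camera did not, with adjusted p = 0.163 for immediate early genes, 0.188 for NRF2 targets, 0.257 for ribosome biogenesis and 0.367 for heat shock.

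Markers of other cell types moved as well. None of 18 hepatocyte markers passed singly, but 8 rose when adjusted over the list alone (median 1.59, camera adjusted p = 3.13e-07, and adjusted p = 0.551 with an estimated correlation), among them the apolipoprotein gene Apoa1 (3.78-fold higher, adjusted p = 0.0849). The mean hepatocyte marker level of the bile duct arrays was 6.93 ± 0.912 with ANIT and 5.66 with vehicle (exact permutation p = 0.0873, BH 0.366). Lists of genes that hepatocytes express were higher beside them, with no member passing. CAR and PXR targets and other xenobiotic cytochromes had a median of 0.59 (24 genes, adjusted p = 0.000175, and adjusted p = 0.551 with an estimated correlation). Acute phase proteins had 0.76 (20 genes, adjusted p = 0.0131, and adjusted p = 0.638 with an estimated correlation), and bile acid synthesis and transport genes 0.32 (23 genes, adjusted p = 0.0131, and adjusted p = 0.48 with an estimated correlation). Macrophage and Kupffer cell markers were lower (median -0.53, adjusted p = 0.0166, and adjusted p = 0.638 with an estimated correlation). Of these 13 markers 1, the endotoxin coreceptor gene Cd14, fell when adjusted over the list alone. Of 18 cholangiocyte markers 1 fell, the biliary transcription factor gene Onecut1 (-2.03 ± 0.36, adjusted p = 0.0172), and the list did not pass (median -0.20, adjusted p = 0.0772).

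In all, 178 probe sets passed at 2 h in bile duct, 41 higher and 137 lower, with a lowest adjusted p of 0.000156. With quantile normalization 58 of 155 were higher, and without the 2 ANIT arrays of low spread (replicates 2 and 4, SD 1.762 and 1.878) 90 of 165 were higher. The fit of the 4 bile duct groups gave 137 (37 higher, 110 of the 178 kept), and with array spread as a covariate in it 101 of 153 were higher and 70 of the 178 were kept. Single arrays moved the count widely: without vehicle replicates 1 to 5 in turn it was 57, 77, 12 (all 12 lower), 89 and 83, and without ANIT replicates 2 to 5 it was 286, 74, 37 and 308. Of the 20 genes named by size only Irgm2 and Ncald passed in each of the 10 fits, Hmox1 passed in 7, Srxn1 and Nab2 in 6, Txnrd1 in 5, Akr1b8 in 3, Hbegf, Hsph1, Lrp8, Rasl11b and Cyp1a1 in 2 each and the other 8 in 8 or 9, and the highest adjusted p among the 20 was 0.125. With quantile normalization 16 of the 20 passed, not Hbegf, Lrp8 (adjusted p = 0.0909), Rasl11b (adjusted p = 0.081) and Cyp1a1.

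**Figure D1:**
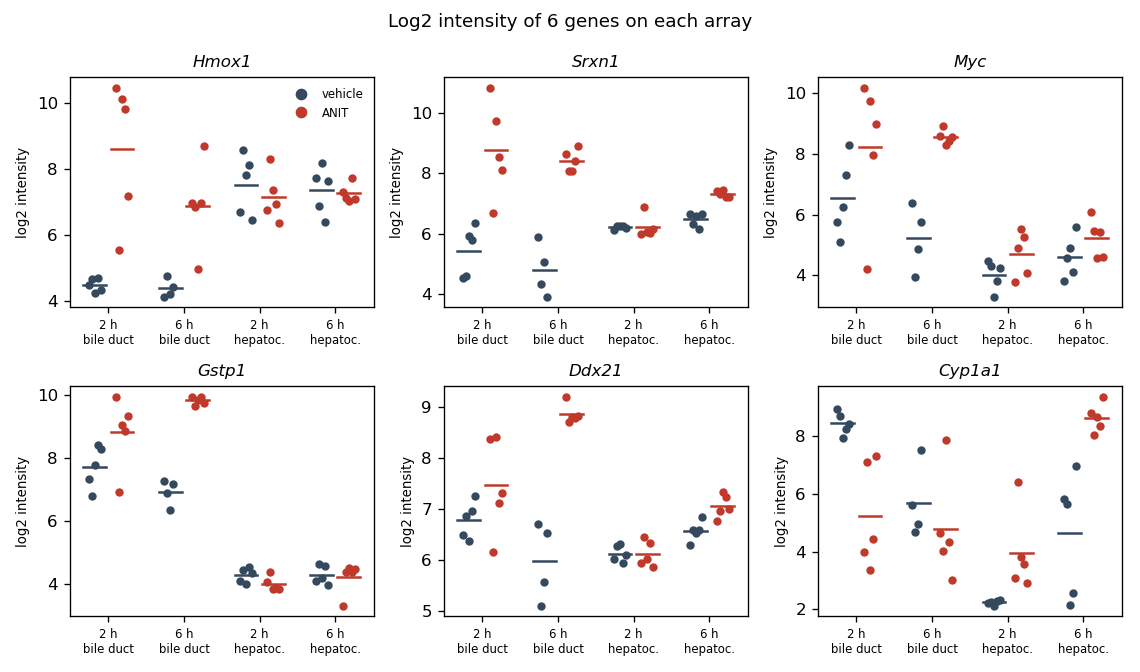
Log2 intensity (vertical axis) of 6 genes on each of the 39 arrays, by time and captured region (horizontal axis), vehicle in a dark colour and ANIT in red, with bars at group means. Srxn1 in bile duct lay between 6.67 and 10.84 with ANIT and between 4.53 and 6.36 with vehicle at 2 h, and between 8.07 and 8.92 against 3.90 to 5.89 at 6 h.

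The matching question in hepatocytes at 2 h gave no probe set past the threshold in limma. The genes with the smallest p were each less than 2-fold different. Smpdl3b, a sphingomyelinase-like gene, was 1.68-fold higher (0.75 ± 0.12, n = 5 and 5, adjusted p = 0.268), followed by Rnpepl1 (1.47-fold), Amigo3 (1.42-fold), Htatip2 (1.34-fold) and Mlec (1.34-fold), with adjusted p from 0.39 to 0.48. Lower without passing were Skil, a repressor of TGF-beta signalling (1.83-fold), the macrophage gene Cd68 (1.44-fold), the citrate synthase gene Cs (1.42-fold), Rbm12b (1.36-fold) and the iron exporter gene Slc40a1 (1.36-fold), each with adjusted p = 0.39. Other probe sets of Cs changed by 0.02 and -0.01, and those of Slc40a1 by 0.01 and -0.29, none passing.

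The bile acid enzyme gene Cyp7a1, which sets the rate of bile acid synthesis, stood at 6.21 ± 0.57 with ANIT and 4.91 ± 0.67 with vehicle (SD), 2.47-fold higher, and passed only when adjusted over the list alone (0.0352, against 0.511 over all probe sets). Cyp1a1 stood at 3.96 ± 1.41 and 2.24 ± 0.08 (0.0325 when adjusted over the list alone, 0.523 over all probe sets). The vehicle value is low and detection calls were not used here, so the size of that difference is not well measured. As lists, unfolded protein and integrated stress response genes were slightly higher (27 genes, median 0.24, camera adjusted p = 3.66e-05), as were ribosome biogenesis genes (median 0.16, adjusted p = 0.00445) and NRF2 targets (median 0.12, adjusted p = 0.0405). Macrophage and Kupffer cell markers were lower (median -0.15, adjusted p = 0.00445). No member passed over all probe sets, 2 macrophage markers (Cd68 and the lysozyme gene Lyz2) fell when adjusted over the list alone, and each of these 4 lists had an adjusted p = 0.748 with an estimated correlation. No list passed with fry. Among the smallest-p members of the unfolded protein and NRF2 lists were Dnajb11 (1.28-fold higher), a chaperone gene of the endoplasmic reticulum, and the glutathione synthetase gene Gss (1.29-fold higher).

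Beside the count of 0 in limma, 1195 probe sets had an unadjusted p under 0.05, against 793 from chance alone, and 2 passed with the p-values of the authors' deposited table after adjustment. Leaving out vehicle replicate 3 or ANIT replicate 3 gave 1 probe set each.

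The question for 6 h was how the bile duct response stood later after the dose. Tnfrsf12a, encoding the receptor for TWEAK, rose from 5.66 ± 1.12 (SD, n = 4) to 9.65 ± 0.21 (n = 5), 15.9-fold (log2 change 3.99 ± 0.42, adjusted p = 0.000392). Srxn1 rose 12.3-fold (3.62 ± 0.38, adjusted p = 0.000392), Atf3 10.7-fold (3.42 ± 0.66, adjusted p = 0.00886), and the growth-promoting transcription factor gene Myc 10.1-fold (3.34 ± 0.41, adjusted p = 0.00102). Ccn2, a matricellular gene induced by YAP and TGF-beta, rose 8.96-fold (3.16 ± 0.56, adjusted p = 0.00643). The largest fall was in Daam2, a formin gene of Wnt signalling, 6.23-fold (-2.64 ± 0.37, adjusted p = 0.00211).

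Also among the largest rises were the transglutaminase gene Tgm1 (10.5-fold), the adhesion receptor gene Pvr (10.0-fold), the epithelial membrane protein gene Emp1 (9.92-fold, with another probe set at 0.31 and not passing), the metalloprotease gene Adamts1 (9.12-fold) and the stomatin gene Stom (8.07-fold), with adjusted p from 0.000392 to 0.00901. Falls of similar rank were in LOC100910558 (5.72-fold), Dhrs3 (5.72-fold), the mitochondrial creatine kinase gene Ckmt1 (5.71-fold) and the thyroid hormone-binding protein gene Crym (5.63-fold). Next came the aldo-keto reductase gene Akr1e2 (5.49-fold), the tubulin-polymerizing protein gene Tppp (5.36-fold), Kndc1 (5.21-fold), the phosphatase gene Ptpn18 (5.07-fold) and the corticosteroid-binding globulin gene Serpina6 (4.95-fold), with adjusted p from 0.00125 to 0.0492. Vehicle means of Atf3 (3.23), Tgm1 (3.45), Adamts1 (3.46) and Emp1 (3.72) were low, so the sizes of their rises are not well measured. Another probe set of Ptpn18 changed by -1.25 (adjusted p = 0.0562). Of these 20 genes all but Kndc1 and Serpina6 passed in each of the 9 fits that left out 1 array. Kndc1 passed in 1 of the 9, with an adjusted p as high as 0.109, and Serpina6 in 4, not passing without vehicle replicate 3 or ANIT replicates 1, 2, 3 or 5 (highest adjusted p 0.0842). Serpina6 also did not pass in the fit of the 4 bile duct groups (adjusted p = 0.0657). It changed by -1.77 (adjusted p = 0.148) with hepatocyte markers as a covariate there and by -1.23 (adjusted p = 0.327) against the 2 h vehicle arrays. Its highest values were on vehicle replicate 3 (8.92) and ANIT replicate 4 (5.84). Those arrays also had the highest hepatocyte marker levels of their groups (9.74 and 8.52).

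Ribosome biogenesis was the list with the smallest p. Of its 19 genes 12 rose, none fell and 7 did not pass, with 13 rising when adjusted over the list alone (median 1.52, camera adjusted p = 1.25e-11, and adjusted p = 0.0296 with an estimated correlation). Examples were the nucleolar genes Ddx21 (7.47-fold, 2.90 ± 0.35), Nop58 (5.47-fold), Fbl (4.02-fold) and Nolc1 (3.33-fold). Of 23 NRF2 targets and glutathione synthesis genes 11 rose and 1 fell, with 15 rising and 1 falling when adjusted over the list alone (median 1.00, adjusted p = 2.08e-07, and adjusted p = 0.154 with an estimated correlation). Gstp1, a glutathione transferase gene, rose 7.46-fold (2.90 ± 0.28, adjusted p = 0.000392), the quinone reductase gene Nqo1 7.31-fold and Gss 5.32-fold. Of 17 heat shock genes 8 rose, and 13 rose when adjusted over the list alone (median 1.20, adjusted p = 4.29e-07, and adjusted p = 0.219 with an estimated correlation), including Hspa4 (3.67-fold), Ahsa1 (3.45-fold), Dnaja1 (3.18-fold) and Chordc1 (3.09-fold), which encode chaperones or their partners. With array spread as a covariate these 4 changed by 0.39, 0.99, 0.10 and 0.48 and none passed, and against the 2 h vehicle arrays Hspa4, Ahsa1 and Dnaja1 changed by 0.39, 0.11 and 0.31 without passing. Of the 4 ribosome biogenesis genes named, 2 passed with the spread covariate (Ddx21 and Nop58) and 3 against the 2 h vehicle arrays (not Fbl, at 0.42). Of the 4 NRF2 targets with the smallest p, 1 passed with the spread covariate (Gstp1) and 4 against the 2 h vehicle arrays.

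Of 25 actin cytoskeleton and adhesion genes 11 rose and 14 did not pass, with 14 rising when adjusted over the list alone (median 0.85, camera adjusted p = 4.29e-07, and adjusted p = 0.219 with an estimated correlation). They included Pdlim7 (5.54-fold), the integrin gene Itgb1 (3.05-fold) and the actinin gene Actn1 (2.97-fold). Itgb1 changed by 0.51 (adjusted p = 0.667) with the spread covariate and by 0.15 (adjusted p = 0.712) against the 2 h vehicle arrays, and Pdlim7 by 1.1 (adjusted p = 0.0574) against the latter. Of 16 tight junction and adherens junction genes 7 rose and 9 did not pass, also 7 when adjusted over the list alone (median 0.78, adjusted p = 0.00087, and adjusted p = 0.266 with an estimated correlation). The claudin genes Cldn4 (7.84-fold) and Cldn7 (7.30-fold), the occludin gene Ocln (3.94-fold) and the E-cadherin gene Cdh1 (2.68-fold) led that list. None of these 4 passed with the spread covariate, and 3 passed against the 2 h vehicle arrays (not Cdh1, at 0.38). Of 24 immediate early genes 7 rose (median 0.41, adjusted p = 0.0219, and adjusted p = 0.454 with an estimated correlation), among them Ier3 (4.47-fold) and Klf6 (2.47-fold), and 8 rose when adjusted over the list alone. Of Atf3, Myc, Ier3 and Klf6 none passed with the spread covariate (Ier3 at 1.02, adjusted p = 0.354, and Klf6 at 0.56, adjusted p = 0.548), and all 4 passed against the 2 h vehicle arrays. Klf6 did not pass with quantile normalization (adjusted p = 0.0751). The MAPK feedback list did not pass (adjusted p = 0.0721), although Dusp5 (6.38-fold), Errfi1 (3.61-fold), Dusp1 (2.97-fold) and Dusp6 (2.91-fold), negative regulators of receptor and MAP kinases, rose. None of these 4 passed with the spread covariate, and all 4 passed against the 2 h vehicle arrays. With quantile normalization Dusp1 (adjusted p = 0.093) and Errfi1 (adjusted p = 0.0971) did not pass. The p53 target list likewise did not pass in camera (adjusted p = 0.0725) but did in fry (adjusted p = 0.0204), with 3 of 10 genes rising: Cdkn1a (7.04-fold), the cyclin gene Ccng1 (3.79-fold) and the stress cytokine gene Gdf15 (3.19-fold). None of these 3 passed with the spread covariate, and 2 passed against the 2 h vehicle arrays (not Ccng1, at 0.62). In the TGF-beta, matrix and fibrosis list 3 of 17 rose, the protease inhibitor gene Timp1 (7.37-fold), Tgfb2 (2.36-fold) and the collagen gene Col4a2 (2.14-fold), none of which passed in either of those settings. The list did not pass in camera (adjusted p = 0.254) but did in fry (adjusted p = 0.0252). The other 6 lists past fry were ribosome biogenesis (adjusted p = 4.29e-05), NRF2 targets (0.000508), heat shock, junction and actin genes (0.00219 each) and immediate early genes (0.0465).

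Some genes of inflammation and bile acid handling fell. In the NF-kB list the adhesion molecule gene Vcam1 (-2.24 ± 0.36, adjusted p = 0.00346) and the chemokine gene Ccl20 (-1.63 ± 0.37, adjusted p = 0.019) fell, while the NF-kB subunit gene Nfkb1 rose 3.72-fold. Ccl20 did not pass in the fit of the 4 bile duct groups (adjusted p = 0.0977), with the spread covariate (0.22) or hepatocyte marker covariate (0.206) there, or against the 2 h vehicle arrays (0.194). Vcam1 passed in each of these, and Nfkb1 did not pass with the spread covariate (adjusted p = 0.175). The other 26 of 29 did not pass, and the list did not pass either (adjusted p = 0.998), with a median of 0.08 and a mean of 0.07 although camera ranked it lower than other genes. Cyp1a1 did not pass at 6 h in bile duct (-0.91 ± 0.78, adjusted p = 0.517). Of 23 bile acid synthesis and transport genes 2 fell, the sterol hydroxylase gene Cyp27a1 (-1.80 ± 0.37) and Nr1h4 (-1.79 ± 0.41), which encodes the bile acid receptor FXR, and 1 rose, the export pump gene Abcc3 (2.27-fold). None of these 3 passed with the spread covariate (adjusted p = 0.0669, 0.132 and 0.252), and all 3 passed against the 2 h vehicle arrays. This list stood lower (median -0.63, camera adjusted p = 0.00104, and adjusted p = 0.425 with an estimated correlation). Interferon targets stood lower with 1 of 18 falling, the antiviral gene Oas1a (median -0.41, adjusted p = 0.017, and adjusted p = 0.425 with an estimated correlation). Oas1a passed with the spread covariate (adjusted p = 0.0327) and not against the 2 h vehicle arrays (adjusted p = 0.103). Neither list passed with fry (adjusted p = 0.13 and 0.11). Of the 47 list members named as passing at 6 h, 36 passed with quantile normalization, 45 in the fit of the 4 bile duct groups, 8 with the spread covariate, 42 with the hepatocyte marker covariate and 31 against the 2 h vehicle arrays.

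Markers of other cells and measures of the arrays moved with ANIT at 6 h in bile duct too. Hepatocyte markers had a median change of -1.6 with none passing, also when adjusted over the list alone (camera adjusted p = 0.0024, and adjusted p = 0.516 with an estimated correlation). Their mean level was 5.92 ± 1.665 with ANIT (n = 5) and 7.29 ± 2.215 with vehicle (n = 4, exact permutation p = 0.302, BH 0.362). Lists that hepatocytes express stood lower beside them. CAR and PXR targets and other xenobiotic cytochromes had a median of -1.06 (camera adjusted p = 0.000185), and 1 of 24 fell, Cyp2c12. Acute phase proteins had -1.16 (camera adjusted p = 0.0201), and none passed. Amino acid and urea cycle enzymes had -0.48 (camera adjusted p = 0.0106), and 1 of 21 fell, the histidine ammonia-lyase gene Hal. PPARA targets and fatty acid oxidation genes had a median of -0.40 (camera adjusted p = 0.017), with 1 of 24 rising, Acadl. With an estimated correlation these 4 lists gave adjusted p = 0.425, 0.524, 0.516 and 0.425. Lymphocyte markers stood lower (14 genes, none passed, median -0.34, adjusted p = 0.0114, and adjusted p = 0.355 with an estimated correlation). Their mean level was low in both groups (2.766 with ANIT and 3.205 with vehicle). With the spread covariate Lck, Cd2, Gzmb and Cd79b changed by -0.32, -0.25, -0.22 and -0.26 without passing. Against the 2 h vehicle arrays Lck, Cd2 and Gzmb changed by 0.08, 0.4 and 0.2 without passing, and Cd79b by -0.71. Of 18 cholangiocyte markers 3 rose, Cldn4, Cldn7 and the annexin gene Anxa2 (4.43-fold), and the mucin gene Muc1 fell (-1.30 ± 0.33), while the list did not pass (adjusted p = 0.127). Of these 4 only Muc1 passed with the spread covariate, and all 4 passed against the 2 h vehicle arrays, while Cyp2c12, Hal and Acadl passed in neither.

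The 6 h vehicle bile duct arrays also differed from the ANIT arrays in overall spread, with a standard deviation of log2 values of 1.812 ± 0.091 (n = 4) against 2.012 ± 0.043 (n = 5, exact permutation p = 0.00794, BH 0.0286). Their mean correlation with arrays of their own group was lower, at 0.866 against 0.932. These values share pairs of arrays within a group, so the exact permutation test (p = 0.00794, BH 0.0286) cannot measure that difference. The B1 repeat probe sets (8.432 against 7.794) and the array median (4.09 against 4.002) were higher with vehicle (exact permutation p = 0.00794, BH 0.0286 for each). The 3' minus 5' actin difference was 4.43 with vehicle and 5.084 with ANIT (exact permutation p = 0.0159, BH 0.0409). That of GAPDH was 4.492 with vehicle and 4.24 with ANIT (exact permutation p = 0.397, BH 0.42).

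In all, 1033 probe sets passed at 6 h in bile duct, 820 higher and 213 lower (79.4% higher). With quantile normalization 402 of 609 were higher, with array spread as a covariate in a fit of the 4 bile duct groups 62 of 162 were higher and 102 of the 1033 were kept, and with the 2 h vehicle arrays as controls 942 of 2247 were higher. Of the 20 genes named by size, 20 passed with quantile normalization, 8 with the spread covariate (the rises Emp1 and Ccn2 and the falls Daam2, LOC100910558, Ckmt1, Crym, Akr1e2 and Ptpn18) and 19 with the 2 h vehicle arrays, while Tnfrsf12a changed by 2.42 (adjusted p = 0.0519) and Myc by 0.81 (adjusted p = 0.607) with the spread covariate. Without vehicle replicate 3 the count was 678, and without ANIT replicates 1, 4 or 5 it was 552, 624 and 598.

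**Figure D2:**
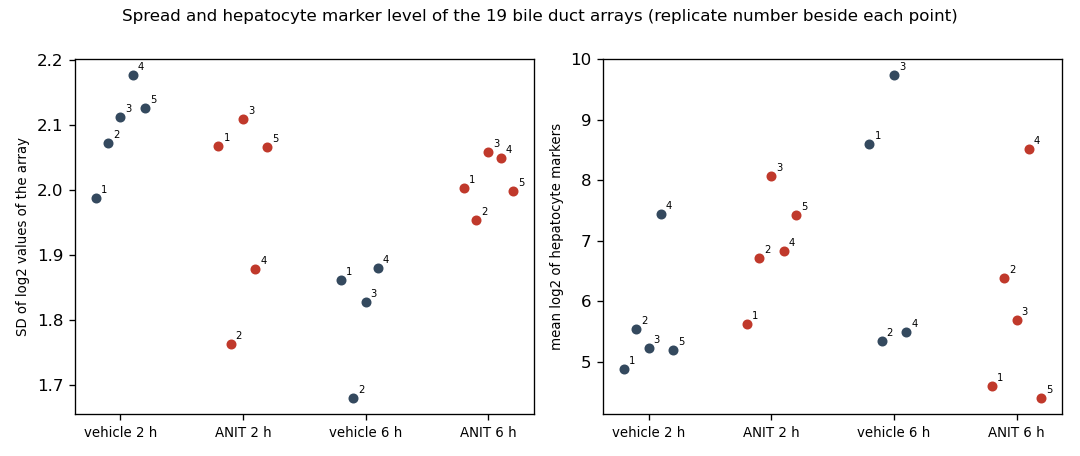
Spread of each of the 19 bile duct arrays (standard deviation of log2 values) and mean log2 level of the hepatocyte markers (vertical axes), by group (horizontal axis), with 1 point per array and its replicate number. The 6 h vehicle arrays spanned 1.679 to 1.879 in spread and the 6 h ANIT arrays 1.953 to 2.058, while hepatocyte markers ranged from 4.40 to 8.52 with ANIT and from 5.35 to 9.74 with vehicle at 6 h.

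In hepatocytes at 6 h no probe set passed in limma, although the smallest adjusted p was 0.0653. Srxn1 stood at 7.33 ± 0.10 with ANIT and 6.47 ± 0.23 with vehicle (SD, n = 5 and 5), 1.81-fold higher (0.85 ± 0.13, adjusted p = 0.0653, 5 of 5 ANIT arrays above the vehicle mean). The aspartate aminotransferase gene Got1 was 2.75-fold higher and Ablim3, an actin-binding protein gene, 2.45-fold higher, with the same adjusted p, and the cell cycle gene Cks1b (1.6-fold) and the CTP synthase gene Ctps1 (1.61-fold) followed (adjusted p = 0.0716). Other probe sets changed by 0.44 for Cks1b and 0.01 for Ctps1. Lower without passing were the bile acid transporter gene Slc10a2 (2.01-fold, adjusted p = 0.0653), Arrdc3 (2.51-fold, adjusted p = 0.0726), Fnip2 (1.65-fold, adjusted p = 0.0952), Tsc22d1 (2.04-fold, adjusted p = 0.113) and Ptprn (1.73-fold, adjusted p = 0.137).

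Of 6 AHR targets, 2 rose when adjusted over the list alone, Cyp1a1 (4.00 ± 0.73, adjusted p = 0.0726 over all probe sets) and Cyp1a2 (1.90-fold higher, 0.92 ± 0.16, adjusted p = 0.0716). Cyp1a1 in the vehicle arrays spread from 2.16 to 6.94, so its size is uncertain. The list had a median of 0.63 (camera adjusted p = 0.000192, and adjusted p = 0.0708 with an estimated correlation). Ribosome biogenesis genes were higher as a list (median 0.35, adjusted p = 2.75e-08, and adjusted p = 0.106 with an estimated correlation), with 8 of 19 rising when adjusted over the list alone, including Nolc1 (1.66-fold) and Wdr43 (1.59-fold). NRF2 targets were higher (median 0.17, adjusted p = 0.001, and adjusted p = 0.0938 with an estimated correlation). Srxn1, Txnrd1 (1.37-fold) and the malic enzyme gene Me1 (1.98-fold) rose when adjusted over the list alone. This Txnrd1 value is from the brighter probe set of the gene, not from that named at 2 h in bile duct. Unfolded protein response genes were higher (median 0.16, adjusted p = 0.0398, and adjusted p = 0.558 with an estimated correlation), with the pseudokinase gene Trib3 (2.62-fold) rising when adjusted over the list alone. With fry 3 lists passed, AHR and NRF2 targets (adjusted p = 0.00562 each) and ribosome biogenesis (adjusted p = 0.0158).

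Cholesterol synthesis genes stood lower with no member passing (16 genes, median -0.25, camera adjusted p = 0.000585, and adjusted p = 0.558 with an estimated correlation), as did fatty acid synthesis genes (19 genes, median -0.21, adjusted p = 0.0374, and adjusted p = 0.624 with an estimated correlation), where Me1 went the other way.

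Beside the count of 0, 1285 probe sets had an unadjusted p under 0.05, against 793 from chance alone. Settings in limma that assume no pairing gave, among others, 14 (eBayes with trend and robust), 8 (without dim probe sets), 6 (1 probe set per gene), 5 (all arrays in 1 fit), 4 (array weights) and 4 (GAPDH covariate). The p-values of the authors' deposited table gave 3 after adjustment. Leaving out vehicle replicate 4 or 5 gave 1 and 2, ANIT replicate 3 gave 1, and ANIT replicate 4 or 5 gave 3 each.

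**Figure D3:**
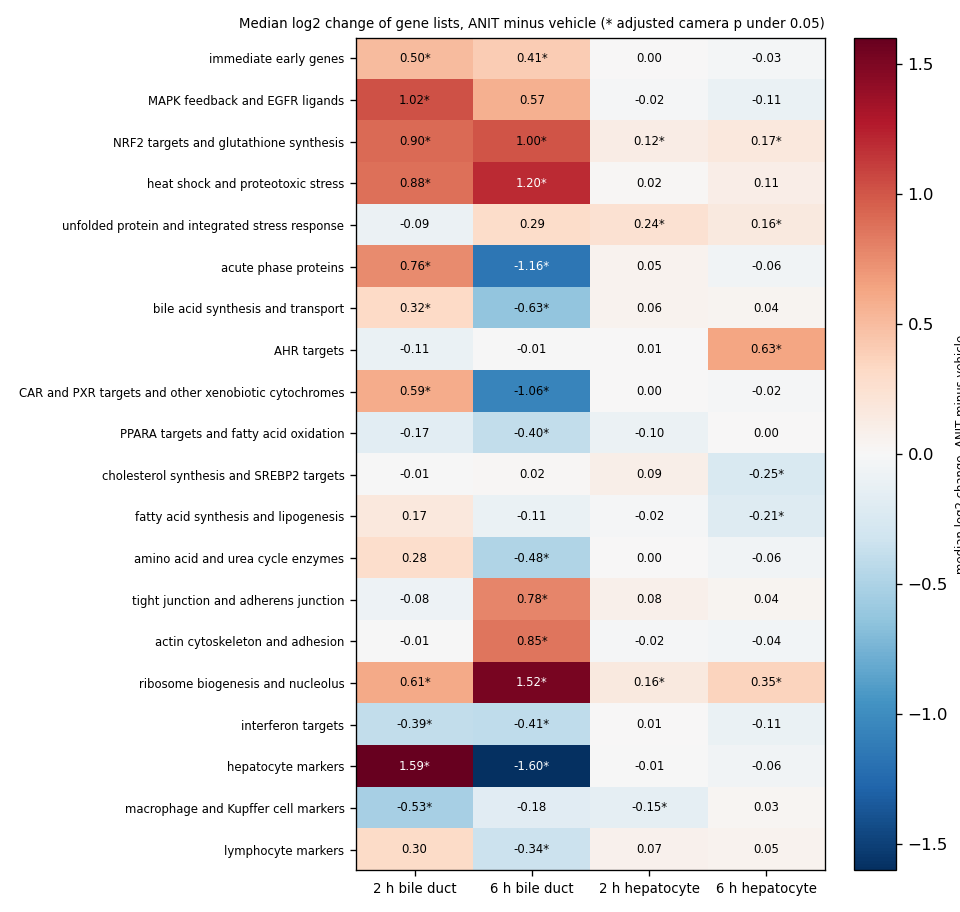
Median log2 change, ANIT minus vehicle, of the gene lists that passed in at least 1 comparison (vertical axis) in each of the 4 comparisons (horizontal axis), in colour from blue (lower) to red (higher), with an asterisk where the adjusted camera p at the preset correlation was under 0.05. Ribosome biogenesis genes had medians of 0.61 and 1.52 in bile duct and 0.16 and 0.35 in hepatocytes at 2 and 6 h, and hepatocyte markers had medians of 1.59 and -1.6 in bile duct.

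Whether bile duct and hepatocytes responded differently was tested directly. At 2 h the ANIT effect was larger in bile duct than in hepatocytes for Hmox1 (difference 4.52 ± 0.94, adjusted p = 0.0234), Srxn1 (3.33 ± 0.71, adjusted p = 0.025), Dusp5 (2.73 ± 0.50, adjusted p = 0.0112), Txnrd1 (2.61 ± 0.58, adjusted p = 0.03) and Hbegf (3.14 ± 0.74, adjusted p = 0.0395). It was lower for Irgm2, which changed by -2.98 in bile duct and 0.02 in hepatocytes (difference -3 ± 0.29, adjusted p = 7.15e-06). For Cyp1a1, at -3.19 in bile duct and, without passing and from a low vehicle level, 1.71 in hepatocytes, the effects also differed (difference -4.90 ± 0.89, adjusted p = 0.0112). The other differences with the smallest p were higher in bile duct for Nudt3, Ier2, Prpf3 and Ppp1r13l (1.39, 1.79, 1.00 and 1.26) and lower for C5h9orf152, Dclk1, the interferon-induced gene Ifi35 and Dolk (-2.06, -1.95, -1.95 and -1.72). In a fit of all 39 arrays Ier2, Prpf3 and Ppp1r13l did not pass (adjusted p = 0.0754, 0.0754 and 0.161). With spread as a covariate within each region these did not pass either, nor did Dclk1 (adjusted p = 0.066).

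At 6 h the ANIT effect was larger in bile duct for Adamts1 (difference 3.10 ± 0.35) and Gstp1 (2.98 ± 0.34), both with adjusted p = 9.07e-05, and for Ppfibp1, the glycyl-tRNA synthetase gene Gars1 and the polyamine synthesis gene Odc1 (2.22, 1.91 and 2.31). Tnfrsf12a (3.82 ± 0.50, adjusted p = 0.000225), Nop58 (2.00 ± 0.27, adjusted p = 0.000225), Ddx21 (2.41 ± 0.36, adjusted p = 0.000523) and Myc (2.70 ± 0.56, adjusted p = 0.00556) were also larger in bile duct. Srxn1 was higher by 3.62 in bile duct and 0.85 in hepatocytes, and these differed (2.77 ± 0.40, adjusted p = 0.000445). Lower in bile duct were Daam2, Ptpn18, Vcam1, Myt1l and Fam117a (-2.90, -2.21, -2.71, -1.85 and -2.15, adjusted p from 0.000225 to 0.000746). For Cyp1a1 the effects also differed (-4.90 ± 1.20, adjusted p = 0.0155). It changed by -0.91 in bile duct and, from widely spread vehicle arrays, by 4.00 in hepatocytes, neither passing. The vehicle bile duct arrays of low spread enter these differences too. In a fit of all 39 arrays with spread as a covariate within each region, Adamts1 (1.97, adjusted p = 0.0569), Ppfibp1 (0.77, adjusted p = 0.407), Srxn1 (1.39, adjusted p = 0.191) and Myc (0.16, adjusted p = 0.947) did not pass and the other 12 did. Without the covariate Myc alone did not pass in that fit (adjusted p = 0.0567).

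In all, 162 probe sets differed in their ANIT effect between regions at 2 h, 38 higher and 124 lower in bile duct, and 1118 at 6 h, 826 higher and 292 lower. These fits take 1 variance per probe set for both regions, although bile duct arrays varied more than hepatocyte arrays. For some genes the standard error of the difference was below that of the bile duct effect alone (Gars1 0.24 against 0.26, Prpf3 0.19 against 0.2). The p-values of these tests can thus be too small and the counts too large, also in the fit of all 39 arrays. With quantile normalization the counts at 2 and 6 h were 148 (58 higher) and 857 (537 higher), with array medians subtracted 84% of 1309 were higher at 6 h, and without the 2 ANIT bile duct arrays of low spread 416 differed at 2 h (214 higher). All 39 arrays in 1 fit gave 95 (27 higher) and 1560 (990 higher), and 150 (102 higher) and 468 (213 higher) with spread as a covariate within each region, which kept 62 of the 162 and 250 of the 1118. Without single arrays the 2 h count was 55, 88, 76, 95 and 75 for hepatocyte vehicle replicates 1 to 5 and 72, 58, 71, 82 and 91 for hepatocyte ANIT replicates 1 to 5. It was 44 for bile duct vehicle replicate 3, and 366 and 463 for bile duct ANIT replicates 2 and 5, and the 6 h count was 1782 without bile duct vehicle replicate 4.

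Change between 2 and 6 h was tested on the effect of ANIT within each region. In bile duct the effect was larger at 6 h for the tubulin gene Tubb5 (difference 2.81 ± 0.43, adjusted p = 0.00314), Mtrex, an RNA helicase gene of the nuclear exosome (2.38 ± 0.36), Sytl2 (2.93 ± 0.48), the podoplanin gene Pdpn (3.57 ± 0.59) and Lrrc42 (2.22 ± 0.38). It was also larger for Emp1 (3.16 ± 0.58, adjusted p = 0.0104), Ddx21 (2.21 ± 0.53, adjusted p = 0.031) and Nop58 (1.49 ± 0.41, adjusted p = 0.0434). It was lower at 6 h for Bfsp1, the general transcription factor gene Gtf2a1, the glycerol phosphate dehydrogenase gene Gpd1, the actin regulator gene Enah and Plxna3 (-2.42, -2.16, -1.99, -2.56 and -2.08). For Srxn1 the effects at 2 and 6 h differed by 0.29 ± 0.79 (adjusted p = 0.846) and for Hmox1 by -1.63 ± 0.99 (adjusted p = 0.305). Hmox1 and Irgm2 passed again at 6 h in bile duct (2.5, adjusted p = 0.0126, and -1.94, adjusted p = 0.0149), and Txnrd1 did not (1.11, adjusted p = 0.15). Of the probe sets higher at 6 h in bile duct, 16 were also among the 41 higher at 2 h, with 2.12 from chance, and 20 of those lower were among the 137 lower at 2 h, with 1.84 from chance. The correlation of the changes at both times across all probe sets was -0.01, with probe sets not independent of each other.

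In all, 566 probe sets differed between times in bile duct, 384 higher and 182 lower at 6 h. With array medians subtracted 78.2% of 660 were higher. The count was 65 with quantile normalization, 2 with array spread as a covariate, 351 with hepatocyte markers as a covariate and 31 without the 2 ANIT arrays of low spread. Without single arrays it was 207, 175, 122 and 181 for vehicle replicates 2 to 5 at 2 h and 941, 187, 866 and 146 for ANIT replicates 1 to 4 at 2 h. It was 224, 304 and 1074 for vehicle replicates 2 to 4 at 6 h, and 242, 247, 240 and 272 for ANIT replicates 1, 3, 4 and 5 at 6 h.

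In hepatocytes no probe set passed the test of change between times in limma. The smallest p belonged to Hivep1, C2cd3, Ctps1, Srxn1 and Cpt2, a mitochondrial fatty acid import gene, whose effects were more positive at 6 h (differences from 0.66 to 0.84, adjusted p = 0.507). Rasgrp2, Hes6, Rnpepl1, Ankrd24 and the desaturase gene Fads1 had more negative effects at 6 h (from -0.88 to -0.56, adjusted p from 0.507 to 0.535). At an unadjusted p under 0.05 there were 1072 probe sets, against 793 from chance alone, and leaving out ANIT replicate 2 at 2 h gave 1.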

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

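The tests of array spread, hepatocyte markers and the 2 h vehicle arrays for the 6 h bile duct rises, of change inside hepatocytes, and of simulated changes for the 2 h hepatocytes were chosen after the results were seen.

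Single arrays lay far from the others of their group in 12 of 224 groups tested (5.36%), about the 1 in 20 that chance gives. In vehicle bile duct at 2 h these were replicate 4 for hepatocyte markers (7.44, others 4.88 to 5.55) and lymphocyte markers (2.49, others 2.72 to 2.80) and replicate 5 for the 3' minus 5' GAPDH difference (4.55, others 3.65 to 3.88). In ANIT bile duct at 2 h replicate 2 stood out for lymphocyte markers (3.56, others 2.68 to 2.88) and Akr1b8 (8.81, others 11.29 to 12.03). At 6 h in bile duct ANIT replicate 5 stood out for cholangiocyte markers (9.01, others 8.84 to 8.88), ANIT replicate 3 for neutrophil markers (3.36, others 3.69 to 3.77), ANIT replicate 4 for Serpina6 (5.84, others 3.77 to 4.14), and vehicle replicate 3 for Serpina6 (8.92, others 5.72 to 6.00) and Stom (2.78, others 4.45 to 4.76). Hepatocyte arrays stood out in the 5S ribosomal RNA probe set (vehicle replicate 1 at 2 h, 2.14, others 2.54 to 2.68) and in the median intensity (ANIT replicate 5 at 6 h, 4.08, others 3.93 to 3.96).

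The ANIT effect differed between regions, by tests of the difference, for 162 probe sets at 2 h and 1118 at 6 h, and between times in bile duct for 566. The region tests pooled the variance of both regions, so their counts may be too large. Among 100 splits of the arrays the real split was alone in reaching its count at 2 h (1 of 100, highest other 60) and for times (1 of 100, highest other 10). At 6 h 2 of 100 reached it, the real split and 1 with 1339, which also kept all ANIT bile duct arrays together. That split differed from the real one only in the hepatocyte labels, so a count this large did not need the true hepatocyte groups. The splits shuffled treatment inside each time and region, so they ask whether ANIT had any effect. An effect in 1 region or at 1 time can put the real split first, so they cannot exclude chance for the difference itself. In probe sets outside the comparisons, 14 of 57 array controls did not overlap between ANIT and vehicle arrays at 6 h in bile duct, 13 lower and 1 higher, with 0.905 from chance, and 0 did so in each of the other ANIT comparisons, with 0.452 from chance.

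More probe sets were higher (820) than lower (213) with ANIT at 6 h in bile duct, and chance was excluded as the source of the count of 1033 (1 of 100 splits, the real one, highest other 119). Hepatocyte RNA was argued against as the source of most calls. In the fit of the 4 bile duct groups 90.9% of the calls were kept with the hepatocyte markers as a covariate. That fit holds more arrays, so part of this share may come from them. Of the 47 list members named as passing, 45 passed in it without the covariate and 42 with it. Against the 2 h vehicle arrays 366 of the 820 also passed as higher, a comparison that shares the ANIT arrays they were chosen on. Lower RNA or array quality of the 6 h vehicle arrays may account for the excess of higher probe sets, as 41.9% of the probe sets passing against the 2 h vehicle arrays were higher, 9.87% of the calls were kept with array spread as a covariate, and 91.6% of the higher probe sets, against 46.5% of all, were higher in the 2 h ANIT arrays of usual spread than in those of low spread. Spread did not overlap between ANIT and vehicle at 6 h, so that covariate also takes up treatment: Ddx21 went from 2.90 to 1.84 (adjusted p = 0.0156) and Myc from 3.34 to 0.81 (adjusted p = 0.607). The 3' minus 5' actin difference was smaller with vehicle (4.43 against 5.084), but so was the 3' actin signal itself (7.675 against 8.632). Differences were also small on the ANIT arrays of low spread at 2 h (2.98 and 4.17 on replicates 2 and 4), whose 3' actin signal was low. The actin difference thus cannot speak for or against lower RNA integrity of the vehicle arrays. A response of the bile duct to ANIT stays open beside lower RNA or array quality, since time also differs from the 2 h vehicle arrays.

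Transcripts typical of hepatocytes were higher at 2 h and lower at 6 h with ANIT in bile duct captures. Of 129 genes at least 16-fold higher in vehicle hepatocytes and in no fixed list, 82.2% were higher at 2 h (median 0.48) and 91.5% lower at 6 h (median -0.71), against 47.9% of all genes higher at 2 h and 50.5% at 6 h. These genes were chosen as low in the vehicle bile duct arrays that also served as controls. That choice favours a rise, so the 82.2% cannot be read alone, while the fall at 6 h went against it. Of 47 genes at least 16-fold higher in vehicle bile duct, where the choice favours a fall, 12.8% were higher at 2 h (median -0.53) and 42.6% at 6 h (median -0.13). A change of these genes inside hepatocytes was argued against, with medians of 0.01 at 2 h and -0.05 at 6 h in hepatocyte captures. A differing share of hepatocyte RNA in the captures may account for the pattern, and whether the capture or a biological change near the ducts led to that was not tested.

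No probe set passed in hepatocytes at 2 h in limma, with 1195 at an unadjusted p under 0.05 and 2 from the authors' deposited table after adjustment. Variation between arrays too large for the test was argued against for 2-fold changes in independent noise, since 91% of simulated 2-fold changes were recovered. Structure shared between arrays was not simulated. Uneven RNA integrity as measured by GAPDH was not settled. With the 3' minus 5' GAPDH difference as a covariate 0 passed, which would also occur with few or no changes to find. The lowest adjusted p was 0.154 with the covariate and 0.268 without, and 1391 probe sets had an unadjusted p under 0.05 with it. All 100 splits gave at least 0, and 1 gave 950 by setting vehicle replicates 1, 3 and 5 with ANIT replicates 4 and 5 apart from the rest, which points to structure of the samples. Those arrays had a GAPDH difference of 3.89 to 4.93 and the rest 2.76 to 3.59, and 1795 probe sets followed it. The 3' minus 5' actin difference of those arrays went the other way (3.62 to 3.94 against 4.00 to 4.60). Their 3' actin signal was lower too (6.38 to 7 against 7.18 to 8.27), so the actin difference cannot be set against that of GAPDH. The source of that structure was not settled. A small response of hepatocytes at 2 h stays open.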

How the results depend on the processing

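The fits of all 4 bile duct groups, their covariates, the spread covariate for regions, the GAPDH covariate, removal of the arrays of low spread and the 2 h vehicle controls were chosen after the results were seen. Where a value moved the cause was not tested, except that fewer arrays or probe sets enter by construction where some are left out. Named genes kept their sign except where listed here. Quantile normalization left 313 of 349 gene results on the same side of the threshold with the same sign, array medians 339 of 349, removal of dim probe sets 273 of 286, the spread covariate 99 of 175, the hepatocyte marker covariate 147 of 175, and single arrays left out 3464 of 3741.

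Counts past the threshold were as follows. Array weights gave 471 at 2 h in bile duct, 4 at 6 h in hepatocytes, 297 and 705 for regions at 2 and 6 h, and 209 for times in bile duct. All 39 arrays in 1 fit gave 1634 and 4564 in bile duct at 2 and 6 h, 5 at 6 h in hepatocytes, 95 for regions at 2 h and 4185 for times in bile duct. This fit lends the smaller variance of hepatocyte arrays to the bile duct tests, so its bile duct counts are too large. In the separate fits the median standard error at 2 and 6 h was 0.281 and 0.346 in bile duct, against 0.113 and 0.153 in hepatocytes. An adjusted p under 0.01 gave 10 and 247 in bile duct. The authors' deposited table after adjustment gave 2 in hepatocytes at 2 h, 618 at 6 h in bile duct and 3 at 6 h in hepatocytes. Quantile normalization gave 609 at 6 h in bile duct (532 of the 1033 kept), 65 for times and 5428 for the captures at 6 h, with Cd8b at -0.01 in the captures at 2 h. Without dim probe sets there were 8 at 6 h in hepatocytes and 5412 and 4773 for the captures, and the median change of all probe sets moved to -0.174 and 0.275 in bile duct at 2 and 6 h. At 6 h in hepatocytes eBayes with trend and robust gave 14, 1 probe set per gene 6 and the GAPDH covariate 4.

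All 4 bile duct groups in 1 fit gave 137 at 2 h and 1697 at 6 h. Array SD as covariate gave 162 at 6 h (102 of the 1033 kept) and 2 for times, and within each region 468 for regions at 6 h, with Cyp1a2 at -0.49 and Aldh3a1 at 0.02. Hepatocyte markers as covariate gave 351 for times and 7 lists at 6 h in bile duct, with Cyp2a2 at -0.10 at 2 h. Without the arrays of low spread there were 416 for regions at 2 h and 31 for times. With 2 h vehicle arrays as controls, 2247 passed at 6 h in bile duct (460 of the 1033 with the same sign) and 4 lists (immediate early, MAPK, NRF2 and ribosome biogenesis), and Cyp1a2 (-0.46), Cyp2c22 (0.01), Acadl (-0.05), Hal (0.17), Col4a2 (-0.08), Ttr (0.48), Cd2 (0.40), Lck (0.08) and Gzmb (0.20) changed sign. Fry left 2, 0, 8 and 3 lists and an estimated correlation 0, 0, 1 and 0 at 2 h bile duct, 2 h hepatocytes, 6 h bile duct and 6 h hepatocytes.

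With 1 array left out, counts ran from 12 to 308 at 2 h and 552 to 1137 at 6 h in bile duct, 0 to 1 and 0 to 3 in hepatocytes, 44 to 463 and 757 to 1782 for regions, 122 to 1074 and 0 to 1 for times in bile duct and hepatocytes, 7421 to 8506 and 7276 to 8614 for the captures. Lists ran from 10 to 15 and 9 to 16 in bile duct, and 3 to 5 and 3 to 12 in hepatocytes. At 6 h in bile duct lists fell to 9 without vehicle replicate 3, and in hepatocytes they were 3 without vehicle replicate 1 and 12 without ANIT replicate 4. Cyp1a2 at 6 h in bile duct ran from -0.05 to 1.67.

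Replicate numbers did not pair the arrays, with correlations across probe sets of their deviations from group means from -0.2 to 0.35, and a replicate block gave 99 and 400 in bile duct at 2 and 6 h, 17 at 6 h in hepatocytes and 68 for times in bile duct. Array numbers in the labels match between regions with an offset of 100, but arrays so matched had correlations from -0.09 to 0.13, too low to pair them. With array number as block, regions gave 141 and 1139 at 2 and 6 h and captures 7979 and 7128.

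Array signal sets limits as well: simulated 2-fold changes were recovered for 30% and 5% of probe sets in bile duct at 2 and 6 h and for 91% and 83% in hepatocytes, and 4-fold changes for 88%, 64%, 100% and 98%. The 1.5-fold threshold moved no count by more than 1.5 times.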

Other observations

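Tests of splits were planned, and no test in this part was chosen after its result was seen. Chance was excluded for the count of 178 at 2 h in bile duct (1 of 100 splits, highest other 45) and for the counts between captures (8286, 1 of 100, highest other 1, and 8515, 1 of 100, highest other 2839). It was not excluded for the numbers of lists: 11 at 2 h in bile duct (34 of 100, highest other 19), 4 at 2 h in hepatocytes (55 of 100, highest other 12), 14 at 6 h in bile duct (18 of 100, highest other 17) and 6 at 6 h in hepatocytes (12 of 100, highest other 10). Counts of 0 at 6 h in hepatocytes (100 of 100, highest other 3) and between times in hepatocytes (100 of 100, highest other 116) are reached by every split.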
